A study of Drosophila melanogaster with 2 samples.

How the data were processed

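Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying, from transgenic flies that express the zinc finger protein Crooked legs (Crol) fused to enhanced green fluorescent protein, per the labels. An antibody against the fluorescent tag was used for the pull-down, although another label field gives crol as the antibody. Chromatin was broken by sonication, per the labels. The 2 libraries are labelled as separate biological replicates of 1 group, and no second condition was compared. A control experiment is named in the labels and was not analysed here.

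The deposited files are peak lists on the dm6 build, per the labels. The authors ranked peaks by the irreproducible discovery rate (IDR), which measures how well the order of peaks repeats between replicates or between parts of the reads, per the file notes. The conservative list holds 9211 peaks that passed between the 2 biological replicates, the optimal list holds 10064 peaks, and the thresholded lists of replicate 1 and replicate 2 alone hold 7813 and 6147 peaks. Longer ranked lists hold the peaks before the threshold, 75620 for replicate 1, 57447 for replicate 2 and 87825 between replicates. The peak caller and aligner are not given in the sources used here. The signal of a peak is the authors' deposited height, with no scaling stated in the file, so signals were compared only within 1 list. The deposited score is a rescaled IDR, and its lowest value in all thresholded lists was 830, which corresponds to an IDR of 0.0099. Read counts are not among the values used, so the sequencing depth of each replicate is unknown, and the intervals given for shares cover counting of peaks or genes only. Peaks are not independent draws of the embryo population, and p-values over peaks or genes describe these lists and not a spread between embryo collections.

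Gene positions came from the Ensembl annotation release 115 of the same assembly, and arm sequences from the RefSeq copy. Every ranked peak ended within the length of its arm in that sequence. The analysis covered 2L, 2R, 3L, 3R, 4 and X, with 18164 genes (13945 protein-coding) after transposable elements were set aside. Of the conservative list, 68 peaks repeat the interval of an earlier peak with another summit, and each was kept. A promoter peak is a summit within 500 bp of any annotated transcription start site (TSS). Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

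The share of summits in promoters was set against 1000 circular shifts of all summits within each arm, with a one-sided empirical p. Signals of promoter and other peaks were compared by a two-sided permutation test of the difference of medians with 100000 resamples. Gene lists, gene classes and X against the 4 large autosomal arms were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 22 lists and over the gene classes. Short sequences of 6 bases (6-mers, reverse complements joined) within 50 bp of the summit were compared with flanks 200 to 250 bp away by an exact McNemar test, adjusted over the 2083 sequences tested, which include 5-base ones fixed in advance. Genes with many peaks were found by an exact Poisson test on the region from 2 kb upstream to the gene's end, with the count expected from length, adjusted over 18164 genes. Shares carry exact Clopper-Pearson 95% intervals, and an upper limit for a count of 0 rests on 3 counts. Peaks of the replicates count as shared when they have at least 1 bp in common.

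The gene lists, tests and the rule for named items were fixed before the data were examined. Named were the nearest genes of the 25 strongest conservative peaks, the 10 genes with the most peaks among those past the threshold, up to 4 members with the strongest promoter peak of each list (all where fewer than 5 had or lacked one), crol with each peak over it, the nearest genes of the 5 strongest peaks found in 1 replicate only, and the 10 6-mers with the highest ratio present in at least 3% of summits. Older gene names were matched to current ones, and 3 of 844 listed names had no protein-coding match. The functions were tested on simulated data. With 9211 random peaks, 0 of 18164 genes, 0 of 2083 short sequences and 0 of 22 lists were called. These peaks were spread evenly along the arms, without the clustering and promoter preference of the real ones. The run therefore does not show how often such features alone lead to calls. With planted peaks, 96% of the planted genes with many peaks were called, and a planted 6-mer had the lowest p of all sequences tested. In that run 33 of the 2083 sequences were called.

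Alternatives were other peak lists (the optimal list, the strongest part of the conservative list, the list of each replicate alone), other promoter windows, protein-coding TSSs only, other rules of overlap and assignment, other windows and backgrounds for the 6-mers, and 10000 random lists matched on the number of TSSs and on gene length. A list with only the highest score, a list that adds left-out peaks, a comparison of equal numbers of peaks per replicate, and gene classes without a nearby coding TSS were chosen after seeing the data.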

Results

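Binding of Crol, a zinc finger protein encoded by the ecdysone-regulated gene crooked legs (crol), was mapped by ChIP-seq through a fluorescent tag in whole embryos of 0 to 24 h. The group held 2 biological replicates. The joint conservative list had 9211 peaks, with a median width of 410 bp and a median signal of 113 in the authors' units. Its peaks covered 2.42% of the 6 arms. The depth of the libraries is unknown, since no read counts were used.

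The replicates shared most of their peaks. Of the 7813 peaks of replicate 1, 68.1% (95% interval 67.1 to 69.2) overlapped a peak of replicate 2, and of the 6138 peaks of replicate 2 on the arms, 84.5% (83.6 to 85.4) overlapped a peak of replicate 1. Shifted peaks overlapped in 3.05% and 3.86% on average over 100 shifts. Peaks of replicate 1 that were shared had a median signal of 96.8, against 50.6 for the others. Across the 87125 peaks matched between replicates in the ranked list, log2 signals had a Pearson r of 0.656 and a Spearman rho of 0.480, and across the 9391 of them past the score threshold the values were 0.884 and 0.804. These correlations are across peaks, which are not independent replicates. The threshold was set on how well ranks repeated between the replicates, so the values past it were selected for agreement. Of all matched peaks, 68.3% differed by no more than a factor of 2 between replicates.

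A few peaks were found in 1 replicate only, even against the long ranked list of the other. Replicate 1 had 247 such peaks (3.16%) and replicate 2 had 74 (1.21%). The strongest in replicate 1 lay in an intron of Hr39, a nuclear receptor gene, at 2L from 21250446 to 21250716 with a signal of 275, where the nearest TSS was that of l(2)k14505. Others in replicate 1 lay near lncRNA:CR42696 (244), at the promoter of ap (243), at the promoter of CG32369 (228) and in an intron of zfh2 on chromosome 4 (224). In replicate 2 the strongest lay in an intron of CG32354 (158), in the 5' UTR of DIP1 (147), at the promoter of Gfat1 (112), in an intron of Dad with Ns1 as the nearest TSS (94.5) and upstream of Sfp33A1 (92.8).

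The 25 strongest peaks of the conservative list had signals from 1556 to 2954. The strongest of that list was at the promoter of tou (toutatis, a chromatin remodelling protein), 2R from 11604881 to 11605490, with a signal of 2954 and its summit 224 bp from a TSS. A peak of 3274 at a TSS of tara passed the same score in the ranked list between replicates and was not part of the conservative list. The second of the conservative list lay in an intron of sty (sprouty, an inhibitor of receptor tyrosine kinase signalling) on 3L from 3418301 to 3418931 with 2678. Intronic peaks of high signal were also found in psq (2204), Atpalpha (1862), sbb (1740), CG2765 (1730) and MEP-1 (1580), and an intergenic peak 18627 bp from the nearest TSS, that of the Polycomb group gene Su(z)2, reached 2183. Near brk (brinker, a repressor of Dpp target genes) 2 peaks of 2127 and 1765 lay 6772 and 1171 bp from its TSS, inside introns of CG1677 and lncRNA:CR44357. Besides those of tou and crol, promoter peaks among the 25 strongest were those of Pka-R2 (2122), CG13204 (1912), Eip75B (1858), tRNA:Ser-TGA-2-1 (1707), CG10492 (1639) and Atxn7 (1556). Apart from an intronic peak of crol (2255), the remaining ones had as nearest genes lncRNA:CR44761 (2274), lncRNA:CR43963 in an intron of Smr (2044), CG31668 (2012), CG5953 (1793), lncRNA:CR44810 (1707), CG33798 (1569) and a short non-coding entry inside CG5953 (1870). Of the 25 strongest peaks, 8 had a TSS within 500 bp and 12 lay in introns. Those nearest to sty, CG2765, CG5953, Atpalpha, MEP-1 and lncRNA:CR44810 lay 565 to 920 bp from a TSS, and the rest lay farther away.

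The gene crol itself carried 9 conservative peaks, against 1.18 expected from its length (Poisson exact test, adjusted p = 0.00127). The gene lies on the minus strand of 2L from 11794327 to 11809438. The third strongest peak of the conservative list, with a signal of 2307, spanned 11808722 to 11809516 with its summit 14 bp from a TSS, and a weaker summit of 170 lay in the same interval. The fifth strongest, with 2255, lay in an intron from 11806557 to 11807304. Peaks of 1246 in the 5' UTR (11807536 to 11808312) and 1036 in an intron (11804513 to 11805034) followed, and an intronic peak from 11806135 to 11806521 had 129. Coding exons held peaks of 86.5 (11799168 to 11799577), 73.6 (11802802 to 11803211) and 12.98 (11803024 to 11803433). The intervals of 73.6 and 12.98 overlap and carry the same replicate signals (35.7 and 47.2). The Poisson test counted each of the 9 summits as a separate peak. In the replicates' own values, the TSS peak had signals of 992 and 1335, and the strong intronic peak 901 and 1341.

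**Figure D1:**
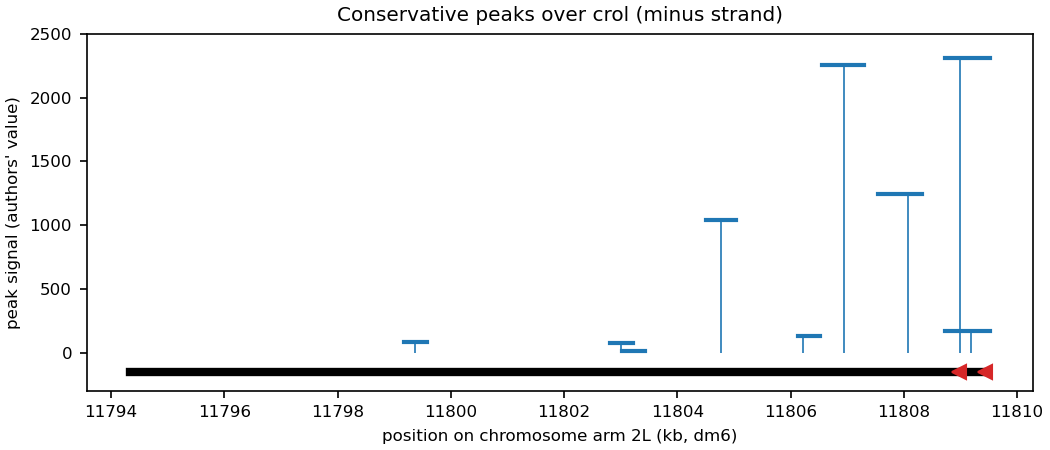
Conservative peaks over crol on 2L, with position in kb (dm6) on the horizontal axis and the authors' peak signal on the vertical axis. Horizontal bars span the peaks, thin lines mark summits, the black bar is the gene and the red arrowheads are its TSSs; 4 of the 9 peaks exceed a signal of 1000, all toward the 5' end.

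Peaks were concentrated at promoters and in introns and were rare in coding exons. Promoters held 2531 summits, 27.5% (95% interval 26.6 to 28.4), against 13.5% in shifted lists (empirical one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Introns held 48.4% of summits against 39.4% in shifted lists, and 5' UTRs 1.10% against 0.608%. Coding exons held 1.95% against 13.8%, 3' UTRs 1.26% against 4.45% and intergenic sequence 18.7% against 27.3% (permutation p = 0.001 for each). Shifted summits can also fall in transposable elements, where 5.84% of them lay, against 0.0651% of the real summits. Whether reads could be placed there was not examined, so part of the intergenic difference may reflect this. The median distance from a summit to a TSS was 1724 bp. Promoter peaks had a median signal of 130 (quartiles 82.5 and 229), 1.19 times the 109 of the other peaks (quartiles 77.7 and 179; permutation p = 1e-05, the smallest possible with 100000 resamples).

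Promoter peaks were found at 2564 genes, among them 2156 of 13945 protein-coding genes (15.5%). Of the 22 gene lists, 9 had more promoter peaks than other protein-coding genes and 1 had fewer (Fisher's exact test). Against random lists matched on the number of TSSs and gene length, 3 stayed higher, those of Polycomb target transcription factors, segmentation genes and cytoplasmic ribosomal proteins, and the list of odorant, gustatory and ionotropic receptors stayed lower (adjusted permutation p = 0.0011 for each, at the smallest p that 10000 lists allow).

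Polycomb target transcription factors, which specify body regions and organs, had the highest share. A promoter peak was found at 38 of 56 members (67.9%, 54.0 to 79.7; odds ratio 11.7; Fisher's exact adjusted p = 3.05e-17), led by mirr (1380), tup (1364), mid (1054) and al (492). Segmentation genes, which divide the embryo along its length, had peaks at 20 of 33 promoters (60.6%, 42.1 to 77.1; odds ratio 8.48; exact adjusted p = 3.06e-08), with btd (444), en (431), odd (385) and gsb (186) strongest. In the Polycomb target list, which contains all 8 Hox genes, the Hox genes Dfd (316), Abd-B (299) and lab (103) had a promoter peak. The Hox list of 3 of 8 did not pass by itself (odds ratio 3.28; exact adjusted p = 0.166). It passed in replicate 1 alone (4 of 8; odds ratio 6.57; exact adjusted p = 0.0274), with the optimal list (5 of 8; 8.47; 0.0107) and with peaks from 2 kb upstream to the gene's end (7 of 8; 17.7; 0.00180). It did not pass in replicate 2 alone, with the strongest part of the list, the highest score alone, the left-out peaks added or windows of 250 and 1000 bp (exact adjusted p from 0.0926 to 0.488), or against matched lists, which had 37.96% on average (adjusted permutation p = 1).

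Ecdysone signalling genes, the hormone pathway that regulates crol, had promoter peaks at 17 of 35 members (48.6%, 31.4 to 66.0; odds ratio 5.20; Fisher's exact adjusted p = 2.35e-05). The strongest were at the nuclear receptor genes Eip75B (1858), Hr3 (781) and Hr4 (758) and at Cyp18a1 (969), which encodes an ecdysone-degrading enzyme. Matched random lists had 34.9% on average, and the list did not pass against them (adjusted permutation p = 0.298). Wingless signalling genes had 14 of 33 (42.4%; odds ratio 4.05; exact adjusted p = 5.74e-04), with sgg (876), fz4 (752), gish (429) and the receptor gene fz2 (378), and did not pass against matched lists (adjusted permutation p = 0.479).

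Of the tissue marker lists, those of nerve and of muscle passed the test against other genes. Neural markers had 15 of 29 (51.7%; odds ratio 5.89; Fisher's exact adjusted p = 2.58e-05), with Syt1 (263), elav (197), Sh (190) and brp (172). Muscle and mesoderm markers had 12 of 26 (46.2%; odds ratio 4.71; exact adjusted p = 5.74e-04), with the muscle transcription factor genes Mef2 (986) and lmd (547), then htl (389) and Act57B (323). Neither passed against matched lists (adjusted permutation p = 0.1003 and 0.450), and neural markers did not pass in replicate 2 alone (odds ratio 2.36, exact adjusted p = 0.110) or with the strongest part of the list (5 of 29, 2.01, 0.296). Markers of gut, fat body and blood had 6 of 25, with kay (923), Dll (223), GATAe (167) and Col4a1 (132). Of these, Dll is known for its part in appendage development and is also a member of the Polycomb target list. Those of epidermis and trachea had 5 of 21, with grh (503), rib (276), bnl (217) and Cht2 (147), and germline markers had 3 of 21, which were stau (1230), orb (112) and bgcn (72.6). None of these last 3 lists passed, but gut, fat body and blood markers passed in replicate 1 alone (exact adjusted p = 0.0273), while matched lists had 23.8% on average (adjusted permutation p = 1).

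Polycomb group proteins, which keep developmental genes silent, had 10 of 27 (37.0%; odds ratio 3.23; Fisher's exact adjusted p = 0.0126), with jing (888), Su(z)12 (740), ph-p (512) and Su(z)2 (241). Trithorax group genes and chromatin remodellers had 9 of 29 (31.03%; exact adjusted p = 0.0580), with fs(1)h (403), kis (360), ash2 (263) and Trl (243). Insulator and architectural protein genes had 5 of 24, with Chro (395), Trl (243), Cp190 (159) and pita (153). The Polycomb group list did not pass in replicate 2 alone (exact adjusted p = 0.174), with the strongest part of the list (0.0893), with the highest score alone (0.125), from 2 kb upstream to the gene's end (0.0528) or against matched lists (adjusted permutation p = 0.479). The trithorax list passed in replicate 2 alone (exact adjusted p = 0.0162), with the strongest part of the list (0.0438), the highest score alone (0.0293), the left-out peaks added (0.00656), a 250 bp window (0.0260) and the region from 2 kb upstream (0.0421). It did not pass in replicate 1 alone (exact adjusted p = 0.150), with the optimal list (0.0804), with a 1000 bp window (0.179) or against matched lists, which had 27.7% on average (adjusted permutation p = 1), and the lists were not tested against each other.

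Notch signalling genes had 9 of 26 (34.6%; odds ratio 2.90; Fisher's exact adjusted p = 0.0281), with mib1 (484), E(spl)mbeta-HLH (265), sca (150) and E(spl)mgamma-HLH (140). The odds ratio was 2.73 in replicate 2 alone, where the list did not pass (exact adjusted p = 0.0577), and matched lists had 17.4% on average (adjusted permutation p = 0.142). The list also did not pass with the optimal list, the strongest part of the list, the highest score alone or a 250 bp window (odds ratios 2.26 to 2.40; exact adjusted p from 0.0850 to 0.184). Dpp and EGFR signalling genes had 9 of 29, with strong peaks at aop (1415), spi (865), Dsor1 (802) and brk (650), and missed the threshold (exact adjusted p = 0.0580). JAK-STAT and Hippo genes had 7 of 21 (exact adjusted p = 0.0580), with Diap1 (728), dome (376), Ptp61F (219) and yki (106). The Dpp and EGFR list passed in replicate 1 alone (exact adjusted p = 0.00202), with the strongest part of the list (0.0438), the left-out peaks added (0.00656), a 1000 bp window (7.98e-04) and the region from 2 kb upstream (4.97e-06), but not in replicate 2 alone (0.110), with the optimal list (0.165), the highest score alone (0.102) or a 250 bp window (0.189), or against matched lists, which had 29.0% on average (adjusted permutation p = 1). The JAK-STAT and Hippo list passed with the optimal list (exact adjusted p = 0.0289), the left-out peaks added (0.0209), windows of 250 bp (0.0474) and 1000 bp (0.00330) and the region from 2 kb upstream (1.31e-04), but not in replicate 1 or replicate 2 alone (0.226 and 0.0584), with the strongest part of the list (3 of 21, odds ratio 1.60, 0.540) or the highest score alone (0.102), or against matched lists, which had 22.9% on average (adjusted permutation p = 0.694).

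Cytoplasmic ribosomal protein genes had promoter peaks at 29 of 93 members (31.2%, 22.0 to 41.6; odds ratio 2.498; Fisher's exact adjusted p = 4.73e-04), all of modest signal, with RpL34b (203.2), RpS27 (192), RpL41 (157) and RpL14 (141) strongest. The direction turned with the strongest part of the list (6 of 93; odds ratio 0.661; exact adjusted p = 0.548). The list did not pass in replicate 1 alone (exact adjusted p = 0.0771) or from 2 kb upstream to the gene's end (odds ratio 1.60, 0.0582). Cell cycle genes had 10 of 53, with CycE (607), Cdk4 (309), grp (273) and Dp (271). Heat shock genes had 4 of 23, which were Hsc70-5 (401), Hsp27 (174), Hsp83 (111) and Hsc70-4 (85.9), and proteasome genes had 2 of 32, Rpn8 (96.3) and Rpn3 (78.1). Odorant, gustatory and ionotropic receptor genes, which formed 1 list, had 0 of 179, which allows a share of up to 1.68% (exact adjusted p = 1.21e-12). With a 1000 bp window 5 of them had a peak and from 2 kb upstream to the gene's end 8, and the list stayed lower (exact adjusted p = 1.72e-11 and 2.04e-15). Chorion and yolk protein genes had 0 of 18, which allows up to 16.7% and did not pass (exact adjusted p = 0.151).

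**Figure D2:**
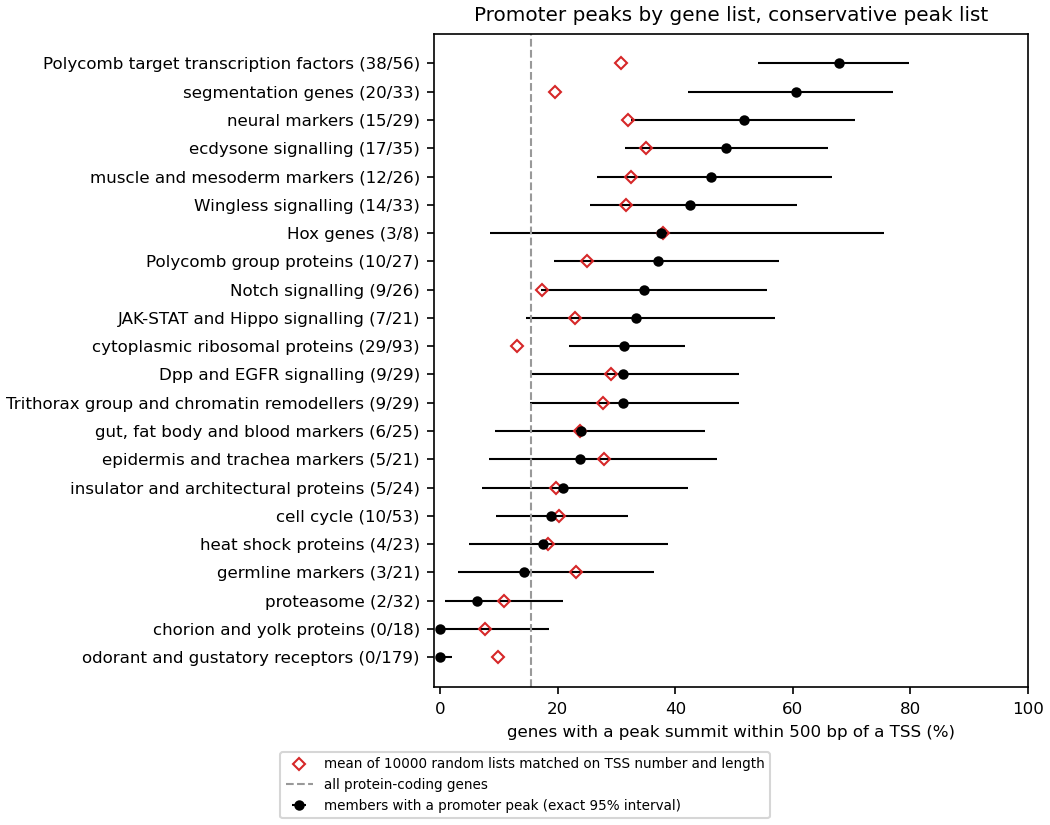
Share of genes with a promoter peak in each of the 22 lists, in percent, with exact 95% intervals (black), the mean of 10000 random lists matched on TSS number and gene length (red diamonds) and the share of all protein-coding genes (dashed line). Polycomb target transcription factors (67.9%) and segmentation genes (60.6%) lie far to the right of their matched lists, and the receptor genes, which include ionotropic ones, lie at 0.

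Non-coding genes had fewer promoter peaks than protein-coding genes. Unlike the gene lists, the classes were not matched on the number of TSSs or gene length, so these may account for part of the difference. Each class was compared with all protein-coding genes. The share was 11.1% for ncRNA genes (363 of 3261; Fisher's exact adjusted p = 3.37e-10), 3.72% for snoRNA genes (10 of 269) and 1.12% for pseudogenes (3 of 268). The snoRNA share was 2.23% in replicate 1 alone, 1.49% in replicate 2 alone and 1.63% for genes away from coding TSSs, and the odds ratio of 0.211 fell to as low as 0.0906. For pseudogenes the odds ratio of 0.0619 ranged from 0.0292 to 0.156 over the alternatives, and both classes stayed lower by the exact test in each. Of the tRNA genes, 29 of 290 had one (exact adjusted p = 0.0125). No rRNA gene had one (0 of 99, up to 3.03%). Whether reads could be placed in genes with several similar copies was not examined, so a missing peak there need not mean a lack of binding. For snRNA genes, 3 of 32 had a peak and the class did not differ by the exact test (adjusted p = 0.465).

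Genes on X had promoter peaks more often than those on the large autosomal arms, in a comparison not matched on the number of TSSs or gene length. The share was 17.9% on X (393 of 2196 protein-coding genes) and 15.1% on the autosomal arms (1761 of 11669), an odds ratio of 1.23 (95% interval 1.08 to 1.38; Fisher's exact p = 0.00105). Peaks of any location numbered 82.5 per Mb on X, 73.3 on 2R, 71.6 on 3L, 63.8 on 2L and 59.0 on 3R. Chromosome 4, which is largely heterochromatic, had 8 peaks (5.93 per Mb) and promoter peaks at 2 of 80 genes.

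Runs of G, or of C on the other strand, marked the summits. The 6-mer CCCCCC was found within 50 bp of 30.3% of summits, and 2639 peaks had it at the summit only against 272 in the flanks only, a ratio of 9.70. The next were AGGGGG (8.22), CCCCTC (7.70), CACCCC (6.77), ACCCCC (6.24), CCCTCC (6.21), GGGGGA (5.98), CCTCCC (5.98), CCCCGC (5.94) and CTCCCC (5.86), with exact McNemar adjusted p of 8.22e-223 or less. The GAGA factor sequence GAGAG was 1.91 times as frequent at the summit only (exact adjusted p = 7.72e-66). The E box CAGCTG had a ratio of 1.34 and the Pho core GCCAT 1.10 (exact adjusted p = 5.20e-05 and 0.0218). Of the 2083 sequences tested, 617 were more frequent at the summit and 797 less. Sequences of G and C without a run of 3 equal bases had ratios of up to 2.21. A pass with a ratio below that does not by itself mark a site of the named factor. TATAAA (0.434), AAAAAA (0.447), the DREF sequence TATCGA (0.633) and the BEAF-32 sequence CGATA (0.762) were less frequent at summits. The Zelda sequence CAGGTA (0.927), the M1BP sequence GGTCAC (1.08) and the E box CACGTG (1.22) did not pass (exact adjusted p = 0.574, 0.525 and 0.205). CAGCTG did not pass in replicate 1 alone (ratio 1.09, exact adjusted p = 0.334), nor did GCCAT in replicate 2 alone (1.03, 0.570), and neither passed with the strongest part of the list (1.19 and 1.12; exact adjusted p = 0.109 and 0.0589). GCCAT missed the threshold with the optimal list (exact adjusted p = 0.0622). At promoter peaks alone, CAGCTG (1.15), GCCAT (1.054) and TATCGA (0.761) did not pass. CACGTG passed with 100 bp on each side (1.42, exact adjusted p = 3.06e-04), and GCCAT had a ratio close to 1 with 25 bp (0.997). A further run compared 2228 promoter peaks with promoters without a peak and of similar GC content, unpaired, by Fisher's exact test. Its ratio sets peaks against those promoters and not summits against flanks, so its size is not comparable with those above. There CCCCCC had a ratio of 15.1. AAAAAA (1.35), CAGCTG (0.725) and GCCAT (0.775) lay on the other side of 1, and TATCGA lay close to 1 (1.047). TATAAA (0.803) and CGATA (0.997) did not pass.

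**Figure D3:**
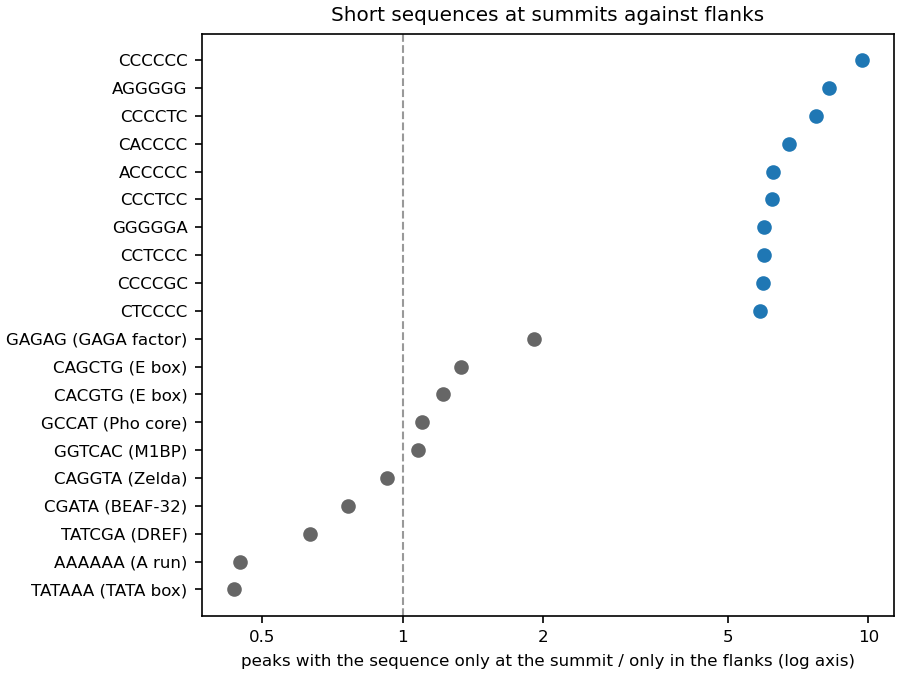
Ratio of peaks with a sequence at the summit only to peaks with it in the flanks only, on a log axis, for the 10 leading 6-mers (blue) and the sequences fixed in advance (grey). The leading 6-mers lie between 5.86 and 9.70, and GAGAG follows at 1.91.

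Several long regulatory genes carried many peaks. Of 18164 genes, 132 had more peaks than their length predicts (Poisson exact test). The gene sbb (scribbler) had 49 peaks against 5.58 expected (exact adjusted p = 4.86e-25), jing 39 against 8.38, the nuclear receptor gene Hr4 32 against 4.68, the homeobox gene hth 32 against 9.22 and the kinase gene Raf 28 against 3.47. Eip75B had 28 against 7.96. The remaining genes among the 10 with the most peaks were lncRNA:CR44357 (41 against 16.6), Glut4EF (28 against 8.44), CG46467 (28 against 7.99) and CG1677 (28 against 8.72). Peaks over Glut4EF and CG46467 lie in overlapping regions, as do those over CG1677 and lncRNA:CR44357, and cannot be assigned to 1 gene. The gene brk lies inside both CG1677 and lncRNA:CR44357. It was the nearest gene of strong peaks there (2127 and 1765), so peaks counted for the pair may belong to brk instead. With the strongest part of the list, hth had 10 peaks and missed the threshold (exact adjusted p = 0.843).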

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

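The ranked list between replicates held 185 peaks that passed the score of the conservative list and were not part of it, which drew attention because they include the highest signal of the ranked list. The gene tara (taranis, a trithorax group gene) had 21 of them, with signals of 3274 at a TSS (3R from 16242368 to 16242941), 2861 and 2619 in 1 intronic interval (16236281 to 16237358) and 1824 in another (16250018 to 16250489). Next came tacc (1588 at a promoter), InR with 10 peaks, Kdm2 with 9 and COX7AL2 with 7. By arm, 43 lay on 2L, 7 on 2R, 5 on 3L and none on X or 4, with 5 on other sequences and the rest on 3R. A candidate explanation is that a fixed set of regions was removed from every thresholded list. Of the 180 on the arms, 4 (2.22%, 95% interval 0.609 to 5.59) shared a base with a thresholded peak of any list, an interval that crosses the limit of 2% set for this explanation, so it stays open. Of the 179 peaks left out for replicate 1 and the 155 for replicate 2, 151 and 128 overlapped those of the joint list. No biological explanation was tested, since the design has 1 group.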

How the results depend on the processing

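The promoter share, the signal difference, the X against autosome difference, the counts of gene classes and of genes with many peaks, and the counts of peaks found in 1 replicate kept their direction and their side of the threshold, or stayed within 1.5 times, in every alternative run. The planned stricter score of 830 removed nothing, since it equals the authors' threshold. Alternatives chosen after seeing the data were the highest score alone, the list with the left-out peaks, equal numbers of peaks and gene classes away from coding TSSs. The shared share of replicate 1 and of replicate 2 was 56.3% and 70.5% with overlap of at least 50% of each peak, 62.1% and 79.0% with summits within 100 bp, 72.2% and 91.0% for the strongest part of each list, and 77.4% and 79.9% with equal numbers of peaks. The Spearman correlation was 0.804 past the threshold, and the linear Pearson r was 0.927. With the strongest part of the list, 1550 genes had a promoter peak, as fewer peaks entered, and the ribosomal odds ratio turned to 0.661 (exact adjusted p = 0.548). That part drops peaks below about the list's median signal of 113, and ribosomal members with a peak had a median of 89.3, so most of them dropped out. Why their peaks were weaker was not tested. Against matched random lists, 3 lists stayed higher and 6 lost the call. The number of central 6-mers was 617 in the main run (9211 peaks), 278 with promoter peaks alone (2531 peaks) and 221 against GC-matched promoters (2228 peaks), where the background changed too. Against the GC-matched promoters, GCCAT (0.775), CAGCTG (0.725) and AAAAAA (1.35) turned direction, and TATCGA lay close to 1 (1.047). GCCAT also lay close to 1 with 25 bp windows (0.997). The cause was not tested. With the left-out peaks, 12 lists were higher. The unknown depth limits what an absent peak means.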

Other observations

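Longer runs of G (or C) had a Crol summit more often, a comparison chosen after the data were seen, as were those of signal and of transposable elements. A conservative summit lay within 50 bp of 9.61% of the 23849 runs of 6 to 7 bases (95% interval 9.24 to 9.99), 15.5% of the 1605 runs of 8 to 9 (13.8 to 17.4), 21.3% of the 1922 runs of 10 to 12 (19.5 to 23.2) and 22.4% of the 1499 runs of 13 or more (20.3 to 24.6). The intervals for 10 to 12 and for 13 or more overlap. Runs of different length were not matched on location, such as coding exons, where summits were rare. Peaks with a run of 6 had a median signal of 126 against 108 for the others (permutation p = 1e-05, the smallest that 100000 resamples give). Such a run was found in 36.6% of the strongest 1000 peaks and 17.2% of the weakest 1000. Annotated transposable elements held 6 summits (0.0651%), against 5.84% in shifted lists (permutation p = 0.001, the smallest that 1000 shifts give). Shifted summits can fall in any sequence. Whether reads could be placed in repeated sequence was not examined, so few peaks there need not mean little binding.

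The runs of G at summits could come from GC content or from promoter sequence. The 16 6-mers made of G and C without a run of 3 equal bases had a median ratio of 1.66 (bootstrap interval 1.51 to 1.93), below the limit of 2 set in advance and far below the 9.70 of CCCCCC, which argues against GC content as the whole cause. At peaks with no TSS within 500 bp the ratio of CCCCCC was 10.4 (9.01 to 11.99), which argues against promoter sequence. A preference of Crol for such runs is a hypothesis that remains, and other proteins at the same sites were not tested.

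The higher density of peaks on X, 82.5 against 66.6 per Mb on the large autosomal arms (ratio 1.24, 1.18 to 1.30), may follow the density of G runs. Runs of 6 or more numbered 318 per Mb on X and 196 per Mb on those arms, a ratio of 1.62 (1.58 to 1.67), which exceeds that of the peaks. Peaks with a run at the summit numbered 30.8 per Mb on X and 18.9 on the autosomal arms, and peaks without one 51.7 and 47.7 per Mb. The autosomal densities do not count the left-out peaks, none of which lay on X. Other differences between X and autosomes were not tested.

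Among the 5 strongest peaks of the conservative list, 2 (2307 and 2255) lie in crol itself, although 3 left-out peaks of tara (3274, 2861 and 2619) exceed both, and extra copies of the region from the tagged transgene might raise them. All positions of the region would then be raised alike, to at least 10 times the usual level if copies were the whole cause. The lower quartile of the 30 ranked peaks within 20 kb of crol was 24.5, against 11.7 for all ranked peaks on the arms, a ratio of 2.09 (bootstrap interval 0.957 to 3.11). The interval lies below 10, which argues against copies as the whole cause, but it crosses the limit of 3 set in advance. A rise by a factor of 2 would fall below both limits and lies inside the interval, so the test cannot exclude it. A rise from copies within the interval, up to 3.11 times, therefore stays open, and so does binding of Crol to its own gene.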
